A study of Arabidopsis thaliana with 6 samples.

How the data were processed

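Gene expression was measured in Arabidopsis thaliana seedlings of the Columbia ecotype on 6 Affymetrix arrays. Per the labels, seedlings grew for 10 d on agar with 16 h of light and 8 h of dark, and were then kept for 8 h in liquid medium. The medium of 3 samples held 1e-07 M 2,4-D, a synthetic auxin. That of the other 3 samples held the same dose of 2,4-D plus 1e-06 M brassinazole, an inhibitor of brassinosteroid synthesis. Groups and replicate numbers came from the sample titles, which call the samples biological replicates. Per the labels, total RNA of a batch came from 3 seedlings and was pooled, and 6 µg of it was turned into biotin-labelled cRNA. Whether each replicate came from its own pool of seedlings is not clear from the labels; if not, the p-values measure only the spread between these samples, which may be technical.

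The deposited values are linear intensities, 1 signal per probe set and array. They were made with MAS5, per the submitters' processing notes; its version, the detection calls and any filter on probe sets are not given in the sources used here. The mean signal over the middle 96% of probe sets was 499.8 on all 6 arrays, close to 500, so the arrays were already scaled to a common level in the deposited values. Such scaling fixes the mean of each array, so a change of most transcripts in the same direction would not be seen. Scanner files were not used here, and the number of arrays, 3 in each group, limits the precision of every value.

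The table held 22810 probe sets, 64 of them Affymetrix controls, which stayed out of the comparison. Names came from the platform annotation given with the values. It gave 1 gene for 13513 probe sets, several genes for 503 and no entry for 8794. Of the probe sets with 1 gene, 13436 matched a RefSeq gene table of the TAIR10.1 assembly, from which symbols were taken. That table served for names only, and no coordinates are given, since no genome build is named for the array. A probe set with several genes or no entry was tested and counted but given no gene name.

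The signals were taken as log2(value + 16), and probe sets whose mean over the 6 arrays lay under the 25th percentile were left out. This left 17059 probe sets, the dimmest with a mean log2 value equal to a signal of 34.2. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Changes are brassinazole plus 2,4-D minus 2,4-D alone. Fold changes are on the log2(value + 16) scale, which understates the change of dim probe sets. Means and SDs are of the signals themselves, over 3 arrays.

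A set of 28 gene lists, holding 513 loci, was fixed before the data were examined. Of these loci, 74 were named by a probe set with 1 gene. Measured members are those with such a probe set left by the filter, so most loci of most lists do not count as measured. Loci without one may lie among the probe sets with no entry. The counts of measured loci thus reflect the annotation given, not what the array holds, and the measured members may not represent their lists. Lists with at least 3 tested members, 12 in all, were tested with camera of limma, with a preset correlation of 0.01 between genes, 1 probe set per gene (the brightest) and Benjamini-Hochberg adjustment over the lists. A further 12 lists had 1 or 2 tested members and are given as values, and 4 lists had no named member. Those were the brassinosteroid synthesis, sterol synthesis, SAUR and auxin transport lists, and they were not analysed here. The same sets were also tested with a correlation estimated from the data and with fry.

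The rule for naming genes was also fixed at that time. In each direction it took the 8 probe sets with 1 gene and the largest change among those past the threshold whose 3 values in a group all lay outside the 3 of the other group. From each list it took up to 4 members past the threshold or, where none passed, up to 2 by smallest p, given as values. It also took the brassinosteroid synthesis genes, for which no probe set was named. Members named beyond this rule, EXGT-A3, CR4, EXO, ARL and AT4G17260, were chosen after their values were seen. Genes of 3 families described among the other observations were chosen after their values were seen.

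The steps were tested on simulated arrays, with 200 of 17059 probe sets changed, over 20 runs. Values were drawn with normal noise from the real means and from the SDs as shrunken by eBayes. The simulated noise thus follows the model of the test more closely than real noise may. The test recovered 64.2% of log2 changes of 0.5, 96.9% of changes of 1 and 100% of changes of 2. Of the calls, 6.73% were false. A list of 10 genes shifted by -0.3 was found in 20 of 20 runs, and an unshifted list was called in 0 runs. Simulated genes were drawn independently of each other, and these lists were judged by unadjusted p. The runs therefore do not show how often the list test makes false calls when genes are correlated. The alternatives tried were quantile scaling, centring on the median, pseudocounts of 1 and 64, no filter, a filter at the 50th percentile, eBayes without the trend and with robust variances. A replicate block, the loss of each array in turn and the removal of probe sets that can bind several transcripts were tried as well. Figures were drawn with matplotlib.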

Results

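The series measured transcripts of whole seedlings given the auxin 2,4-D alone (3 arrays) or 2,4-D together with brassinazole (3 arrays). Its title concerns auxin and the synthesis of brassinosteroids, a class of growth-promoting steroid hormones, in roots. The comparison therefore asks which transcripts of auxin-treated seedlings differ when brassinosteroid synthesis is inhibited. Seedlings without 2,4-D, or with brassinazole alone, were not analysed here, so a change is relative to 2,4-D alone and no response to 2,4-D itself was measured. The median signal of an array lay between 188.8 and 195.6, and the Spearman correlation across probe sets was 0.9875 to 0.9885 within the auxin group, 0.9854 to 0.9893 within the brassinazole group and 0.9808 to 0.9854 between the groups. The first principal component, with 43.9% of the variance, separated the groups. The second, with 18.8%, set brassinazole replicate 3 (-19.6) apart from replicates 1 and 2 (13.3 and 10).

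Auxin-inducible conjugating enzymes and wall-loosening proteins were among the transcripts that fell most in seedlings given brassinazole. GH3.3, an amido synthetase that links auxin to amino acids, fell from a signal of 7533 ± 249 to 1571 ± 113 (SD, n = 3 each), a 4.76-fold difference with a limma adjusted p of 1.78e-09. EXPA8, an expansin that loosens cell walls, fell from 1679 ± 59.0 to 551 ± 44.3. With the pseudocount of 16 used here, the largest rise among named genes was that of AT5G62330, from 112 ± 22.7 to 502 ± 31.0. This rank depended on the pseudocount. With a pseudocount of 1, AT5G39520 and PDF1.2b rose more (log2 changes of 2.223 and 2.189, against 2.177 for AT5G62330). With a pseudocount of 64 they rose less (1.373 and 0.8811, against 1.695). In all, 1282 of 17059 probe sets passed, 586 higher and 696 lower with brassinazole (676 and 609 with arrays centred on their median, which turns the balance), and 110 of them differed at least 2-fold, 45 higher and 65 lower. Of the 1282, 621 were assigned 1 gene, 292 higher and 329 lower. The values of the groups did not overlap in 1275 of the 1282, and in 27.2% of all probe sets tested, where chance gives 10%. The 5S rRNA control probe set was also higher with brassinazole, at 230 to 284 on its 3 arrays against 134 to 174. In 1 of 2 sets of controls, the 3' to 5' ratio, a measure of RNA integrity, was 18.8 to 21.1 with brassinazole against 12.3 to 17.3 for actin, and 2.59 to 3 against 3.14 to 3.54 for ubiquitin. The counts of higher and lower probe sets were 316 and 439 without the variance trend, and 355 and 460 without auxin replicate 1 and brassinazole replicate 3, whose control probe sets stood apart, a choice made after these were seen. With any single array left out, both counts were smaller, at 338 to 527 higher and 452 to 630 lower. The smallest were 378, 382 and 338 higher without auxin 1, auxin 3 or brassinazole 2, and 463 and 452 lower without auxin 2 or auxin 3. Fewer arrays alone give fewer calls, so these counts do not single out particular arrays.

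The measured part of the GH3 family, 4 of 7 loci in its list, fell as a group. All 4 measured members passed, over all probe sets and adjusted over the list alone, with a median log2 change of -1.48 (camera adjusted p = 3.26e-11; adjusted p = 0.0249 with an estimated correlation). Besides GH3.3, GH3.1 fell from 186 ± 1.58 to 44.5 ± 9.69, a log2 change of -1.75 ± 0.158 (SE). WES1, also known as GH3.5, fell from 5514 ± 253 to 2380 ± 85.8, and GH3.17 from 1384 ± 144 to 851 ± 134. The change thus ranged from 1.62-fold for GH3.17 to 4.76-fold for GH3.3, and the 3 values of each member in the brassinazole group all lay below the 3 in the auxin group.

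Genes that act when lateral roots are initiated were lower as well. Of 17 loci in the list, 4 were measured and 3 of these fell. The list passed (median -0.88, camera adjusted p = 0.000296), though not with an estimated correlation (adjusted p = 0.0814). LBD29 and LBD16, transcription factors that act downstream of auxin response factors in lateral root initiation, fell from 245 ± 33.6 to 83.3 ± 2.04 and from 300 ± 20.3 to 126 ± 17.1. PUCHI, an AP2-type transcription factor of the lateral root primordium, fell from 122 ± 17.0 to 75.4 ± 16.4, with an adjusted p of 0.0418. Adjusted over the list alone, the same number, 3, passed. CR4, the receptor kinase also called ACR4, was at 110 ± 5.90 and 112 ± 16.8 (adjusted p = 0.954), and its log2 change of 0.02 turned to -0.01 without auxin 1 and -0.06 without brassinazole 1. The PUCHI call was lost without auxin 1, auxin 2, auxin 3, brassinazole 2 or brassinazole 3, with adjusted p of 0.0647, 0.0982, 0.159, 0.119 and 0.111, with no filter (0.11), without the variance trend (0.0551) and without the 2 arrays whose controls stood apart (0.122).

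**Figure D1:**
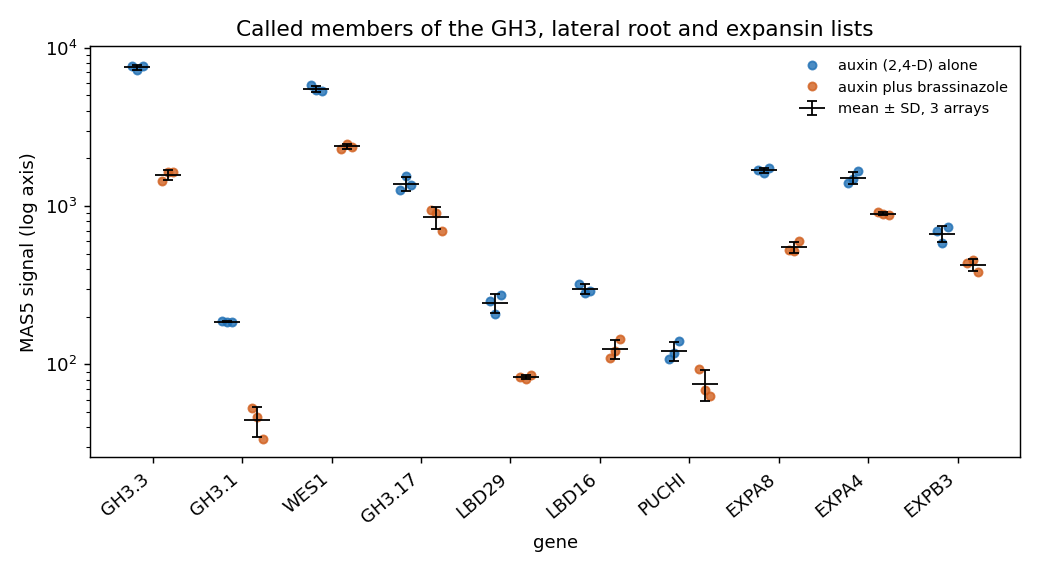
MAS5 signals on a log axis of the 10 members of the GH3, lateral root initiation and expansin lists that passed the test, with a point per array, blue for 2,4-D alone and orange for 2,4-D plus brassinazole, and bars for the mean ± SD of 3 arrays. All orange points of a gene lie below its blue ones, with GH3.3 at 7533 against 1571 and GH3.17 at 1384 against 851.

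Of the Aux/IAA repressors, early auxin response genes, 4 of 28 loci were measured. Over all probe sets tested with limma, 0 of these 4 passed, while 4 passed at an unadjusted p under 0.05 and 4 adjusted over the list alone. Their median was -0.47 and the list passed with camera (adjusted p = 0.0156), but not with an estimated correlation (adjusted p = 0.13) or without brassinazole replicate 3 (adjusted p = 0.0917). IAA30 was at 86.5 ± 10.4 with 2,4-D alone and 53.7 ± 18.7 with brassinazole (adjusted p = 0.0989, and 0.0282 without brassinazole 1), and IAA29 at 155 ± 15.2 and 119 ± 13.4 (adjusted p = 0.142).

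Expansins, proteins that loosen the cell wall during growth, were lower across the measured part of the list, 10 of 19 loci. The log2 change was negative in 10 of 10 measured members; 3 fell past the threshold and 5 did when adjusted over the list alone (median -0.37, camera adjusted p = 1.03e-05; adjusted p = 0.0451 with an estimated correlation). EXPA8 changed most, 3.00-fold. EXPA4 fell from 1515 ± 136 to 895 ± 20.7 and EXPB3 from 671 ± 81.2 to 427 ± 38.2. EXPB2, a beta-expansin outside the list, was among the 8 named genes that fell most, from 545 ± 16.6 to 177 ± 16.9.

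Xyloglucan endotransglucosylase/hydrolases (XTH), which cut and rejoin wall xyloglucan, moved in both directions. Of 8 measured members, out of 27 loci in the list, 4 fell, 1 rose and 3 did not pass. Adjusted over the list alone, 6 passed. The list passed with camera (median -0.49, adjusted p = 0.00724) but not with an estimated correlation (adjusted p = 0.322). XTH19 fell from 782 ± 54.1 to 331 ± 28.8, XTH26 from 90.05 ± 14.3 to 41.0 ± 9.28, XTH16 from 677 ± 40.4 to 415 ± 89.5 and EXGT-A3, also called XTH27, from 4440 ± 379 to 3415 ± 284. XTH18 rose from 308 ± 42.3 to 448 ± 69.0, a log2 change of 0.51 ± 0.126 (SE) with an adjusted p of 0.0236. The list call was lost without auxin 2 (0.0571) and with no filter or one at the 50th percentile (0.055 and 0.123). The XTH18 call was lost without auxin 1, auxin 2, brassinazole 1 or brassinazole 3 (adjusted p = 0.0979, 0.0899, 0.0973 and 0.0574), with no filter (0.0768), without the variance trend (0.0804) and without the 2 arrays (0.154). That of XTH26 was lost without auxin 2 or auxin 3 (0.0518 and 0.0533), and that of XTH16 without the 2 arrays (0.0529). That of EXGT-A3 was lost without auxin 1, auxin 2 or brassinazole 2 (0.0744, 0.0849 and 0.0552), with no filter (0.053), without the variance trend (0.0891) and without the 2 arrays (0.126).

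Among genes known to be induced by brassinosteroids, 5 of 23 loci were measured. Of these 5, 2 fell and 1 rose, and 4 passed adjusted over the list alone. The 3 that passed over all probe sets, EXPA8, XTH19 and XTH18, belong to the wall lists too, so this list is not separate evidence. EXO, a wall protein, was at 2343 ± 293 and 1933 ± 51.5 (adjusted p = 0.101, and 0.0277 without auxin 3), and ARL at 2357 ± 112 and 2504 ± 209 (adjusted p = 0.621). The list passed with camera (median -0.27, adjusted p = 0.0139), not with an estimated correlation (adjusted p = 0.13) or without the 2 arrays whose controls stood apart (adjusted p = 0.0598). BAT1, an acyltransferase thought to inactivate brassinosteroids, fell from 943 ± 58.5 to 652 ± 50.5 (adjusted p = 0.00253) and was the only measured member of its list. For brassinosteroid signalling, BRL1 and BIM1 had log2 changes of -0.20 and -0.16 and did not pass (adjusted p = 0.459 and 0.469).

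Beyond these lists, genes of diverse kinds differed most. AT2G23060 fell from 274 ± 32.1 to 68.4 ± 16.3, AT4G38410 from 434 ± 59.3 to 119 ± 19.7, AT4G37290 from 73.6 ± 6.57 to 15.4 ± 8.32 and AT1G34510, a class III peroxidase, from 179 ± 7.38 to 51.2 ± 4.45. AT5G39520 rose from 49.6 ± 15.3 to 229 ± 26.2, and AT2G47880, a glutaredoxin, from 315 ± 18.8 to 852 ± 26.7. PDF1.2b, a plant defensin, rose from 20.2 ± 8.91 to 90.8 ± 9.39; its probe set can bind related transcripts. ATGSTF13, a glutathione transferase, rose from 39.2 ± 2.43 to 135 ± 27.4, AT3G27950 from 75.9 ± 6.13 to 200.4 ± 37.5 and AT3G60420 from 67.4 ± 5.34 to 195 ± 1.66. AT3G01430 rose from 27.2 ± 25.6 to 85.8 ± 11.6, with an adjusted p of 0.0135 that went to 0.0555 without auxin 2, 0.0732 without auxin 3, 0.0652 with no filter and 0.0534 without the variance trend. Of the probe sets with no gene assigned here, 266 rose and 361 fell.

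No difference was detected in 6 other lists tested with camera. The cell cycle, gibberellin, flavonoid, xenobiotic detoxification and reference gene lists each had an adjusted p of 0.593, and the photosynthesis list one of 0.988. With limma, 0 members of these lists passed over all probe sets or adjusted over the list alone. The measured members were few: 3 of 23, 3 of 23, 3 of 15, 4 of 29, 4 of 12 and 3 of 32 loci, in that order. These results therefore do not cover the pathways as a whole. Among their members, AUR1, a mitotic kinase, was at 384 ± 35.8 and 431 ± 18.7, the gibberellin receptor GID1C at 219.5 ± 32.8 and 191 ± 35.0, and DFR, an enzyme of anthocyanin synthesis, at 73.7 ± 6.13 and 51.8 ± 9.15. UGT73B4, a glycosyltransferase induced by xenobiotics, was at 371 ± 14.9 and 423 ± 24.1. RCA, which encodes Rubisco activase, was at 25000 ± 666 and 26080 ± 3053, a log2 change of 0.05 that was -0.03 without brassinazole 3. The reference gene PEX4, also called UBC21, was at 976 ± 65.6 and 1126 ± 80.7.

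Lists with 1 or 2 measured members were given as values. PDC2, a pyruvate decarboxylase of the hypoxia list, rose from 977 ± 132 to 1516 ± 270.2 (adjusted p = 0.00817), which was lost without auxin 3 (0.0535) or the variance trend (0.0622). The other measured member of that list, AT4G17260 (LDH1), a lactate dehydrogenase, was at 545 ± 56.8 and 431 ± 41.2, with an adjusted p of 0.0823 (0.0438 without brassinazole 3) and 0.00847 adjusted over the list alone. PYK10, an abundant root beta-glucosidase, was at 15030 ± 2088 and 15910 ± 1430 (log2 change 0.09 ± 0.1, SE). The root hair expansins EXPA7 and EXPA18 had log2 changes of -0.37 and -0.44 and did not pass over all probe sets (adjusted p = 0.0916 and 0.0806; EXPA18 0.0238 without auxin 3), though both did adjusted over the list alone. Log2 changes that did not pass were 0.67 for PDF1.2 and 0.15 for THI2.1 (jasmonate), 0.54 for WRKY53 (salicylate), 0.25 for RR16 (cytokinin) and 0.11 for COR15A (dehydration). Those of EIN3 (ethylene), GI (circadian clock) and the heat shock genes AT5G51440 and AT5G37670 were -0.09, 0.21, 0.29 and 0.20. Adjusted over the list alone, PDF1.2 passed (0.0305), and without auxin 3 it passed over all probe sets too (adjusted p = 0.0139). WRKY53 and GI were the only measured members of their lists, so no adjustment over the list was possible. Their unadjusted limma p was 0.0468 and 0.0205, and their adjusted p over all probe sets 0.221 and 0.137.

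**Figure D2:**
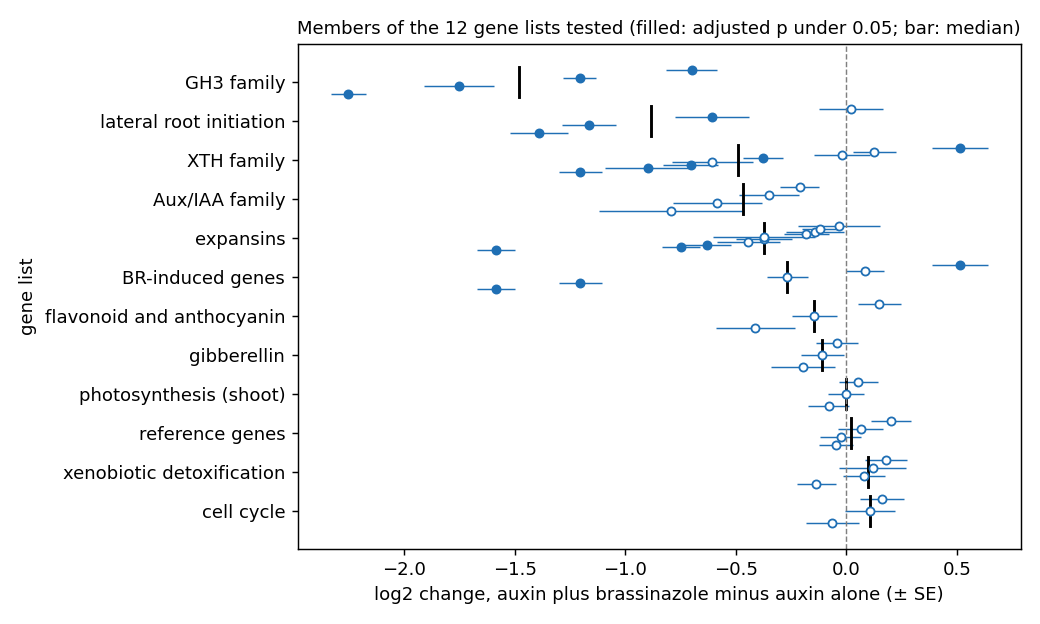
Log2 change (2,4-D plus brassinazole minus 2,4-D alone) of each measured member of the 12 gene lists tested, with its SE; filled points passed the test over all probe sets, open points did not, and the black bar is the list's median. The GH3 list has the lowest median, -1.48, with GH3.17 at -0.70 and GH3.3 at -2.25, while the photosynthesis and reference gene members lie close to 0.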

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

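The control probe sets, which took no part in the comparison, were tested between the groups after the main result was seen, and 3 of 60 passed. The 5S rRNA control was higher with brassinazole by a log2 change of 0.6738 (adjusted p = 0.0219), and the 3' GAPDH and middle ubiquitin controls by 0.3689 and 0.3733 (adjusted p = 0.0185 each). Other probe sets of the same transcripts did not pass, among them the middle and 5' GAPDH controls (0.17 and 0.15, adjusted p = 0.225 and 0.34) and the 3' and 5' ubiquitin controls (-0.20 and 0.06, adjusted p = 0.343 and 0.67). The ratio of these 3' to 5' GAPDH controls was 1.26 to 1.41 with 2,4-D alone and 1.38 to 1.69 with brassinazole (exact permutation p = 0.3, two-sided). That of the matching actin controls was 12.3 to 17.3 and 18.8 to 21.1, and that of the ubiquitin controls 3.14 to 3.54 and 2.59 to 3 (exact permutation p = 0.1 each, the smallest that 3 against 3 arrays can give). In the array's other set of controls for the same transcripts, these ratios were 1 to 1.2 and 0.999 to 1.11 for GAPDH, 2.31 to 2.52 and 2.21 to 2.43 for actin, and 1.25 to 1.42 and 1.26 to 1.43 for ubiquitin (exact permutation p = 0.6, 0.4 and 1). No explanation was tested for these differences.

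The 25S rRNA control was at 981 on the auxin 1 array and at 174 to 215 on the other 5 arrays. On the brassinazole 3 array, the spiked bioB, bioC and bioD controls read 338, 285 and 3800, against at most 204, 186 and 2746 on the others. No test of single arrays was run, and these values are given without an explanation.

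The GH3, lateral root and expansin lists had the lowest camera adjusted p of the 12 tested. Their genes together were lower with brassinazole, with a median log2 change of -0.617 over 18 members, so this pooled fall is not separate evidence. The brassinazole 3 array stood apart from its group. Over the 10 members called lower, the median log2 difference from the auxin mean was -1.29, -1.17 and -1.1 on brassinazole 1, 2 and 3. The members differed, however. LBD16, LBD29 and EXPA8 fell least on brassinazole 3, while GH3.1, GH3.17, PUCHI, EXPA4 and EXPB3 fell most there. Over all 18 members, the median was -0.617 with that array and -0.539 without it. These medians therefore do not show whether the array made the fall larger or smaller. The test, set before its result was read, asked whether the median without that array stays below -0.308 by more than 2 standard errors. Its SE is taken over the 18 genes, which share the same arrays, and not over arrays. At -0.539 ± 0.19 (SE) the test did not decide. Read after that result, the planned fits without the array left all 3 lists lower and past the threshold (camera adjusted p = 7.95e-11, 0.000435 and 9.49e-06). For these lists, this argues against the array as the only source of the fall. In a test chosen then, 9 of the 10 members called lower stayed called, all but PUCHI. These members were picked as called on the same arrays, so most were likely to stay called. PUCHI also lost its call without other single arrays, so no conclusion is drawn from that test. With all arrays and an estimated correlation, the lateral root list did not pass (camera adjusted p = 0.0814). A smaller share of root tissue would lower root transcripts alike. The 12 root-enriched genes tested for this, many of them class III peroxidases, had a median of 0.0853 ± 0.16 (SE over genes). This lay above -0.308 by more than 2 standard errors, with 2 genes higher and 2 lower. Their log2 changes ran from -0.61 for AT4G26010 to 0.80 for AT4G30170. The list thus showed no common fall, but genes that move both ways cannot measure the share of root tissue, so this explanation stays open. An effect of inhibited brassinosteroid synthesis may remain as an untested hypothesis, as does another effect of the compound; seedlings given brassinosteroid back, which could tell these apart, were not analysed here.

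Of the 10 ways to split the 6 arrays into 3 and 3, the real one called 1282 probe sets, the highest other 0, and 1 split gave as many as the real one, itself. With 10 splits the share cannot go under 0.05, so they are too few to test chance.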

How the results depend on the processing

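The removal of the 2 arrays, and all runs for the families, for named genes not past the threshold and for genes named beyond the naming rule, were chosen after the data were seen; the other alternatives were set before. Over 17 alternatives, 0 of the 40 named genes past the threshold turned direction in the 659 runs that gave a value. Another 21 gave none, as the probe set was under the filter or left out. The groups did not overlap in any of these genes, so the loss of arrays or another pseudocount could not turn a direction. The filter, variance, block and probe set settings do not alter a log2 change. Only quantile scaling and centring could thus have turned a direction. The GH3 and expansin lists passed under all alternatives run for them. The higher and lower counts were 316 and 439 without the variance trend, 355 and 460 without auxin 1 and brassinazole 3, and ranged over 338 to 527 and 452 to 630 with each array left out, where fewer arrays were tested. Other settings kept both counts within 1.5 times, such as quantile scaling (617 and 653) and centring on the median (676 and 609), but the latter turned the balance to more higher than lower. With an estimated correlation, the adjusted p was 0.13 for Aux/IAA and for brassinosteroid-induced genes, 0.0814 for lateral root initiation and 0.322 for XTH. Without the 2 arrays it was 0.13 for Aux/IAA and 0.0598 for brassinosteroid-induced genes. For XTH it was 0.055 with no filter and 0.123 with a filter at the 50th percentile, where 9 and 6 members were tested. With each array left out it ranged over 0.00794 to 0.0917 for Aux/IAA (highest without brassinazole 3) and 0.000724 to 0.0571 for XTH (highest without auxin 2). The photosynthesis list, never past the threshold, turned direction when arrays were centred (0.966), without the 2 arrays (0.801) and without auxin 1 or brassinazole 1 (0.74 and 0.784; range 0.74 to 0.853). Apart from the fewer arrays or members named, the cause was not tested. These 40 genes lost their call in 34 runs: PUCHI in 9, XTH18 in 7, EXGT-A3 in 6, AT3G01430 in 4, AT5G11930 in 3, PDC2 and XTH26 in 2 each and XTH16 in 1 (adjusted p = 0.0529 without the 2 arrays). Of the 26 named genes not past it, 5 passed in 1 run each. The log2 change of CR4 turned to -0.0083 without auxin 1, -0.0601 without brassinazole 1 and -0.0311 without the 2 arrays, and that of RCA to -0.0264 without brassinazole 3 and -0.00457 without the 2 arrays.

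The labels name no pairing of the samples by replicate number. Deviations of same-numbered arrays correlated at 0.04, 0.06 and 0.05, and those of other numbers at -0.01 or below. Each array thus correlated best with its own number, a hint from the data and not the design. These small values do not settle whether the numbers pair the samples. With the replicate block, 604 were higher and 676 lower, and of these 40 genes only PUCHI lost its call (adjusted p = 0.0671). The alternatives for the brassinosteroid synthesis genes were not run, as no probe set was named for them. Detection calls were not used here, so how far dim signals stood above background was not measured.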

Other observations

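The gene families below were chosen after the main comparison was seen, and the tests on members not seen before were set before those values were read. Pectate lyase-like genes, whose products cut pectin in the cell wall, fell as a family: 8 of 14 measured members fell and 0 rose (median log2 change -0.447, camera adjusted p = 1.79e-08; adjusted p = 0.0135 with an estimated correlation). AT1G67750 fell from 2393 ± 53.0 to 1006 ± 35.0 and AT3G07010 from 956 ± 67.5 to 436 ± 46.7 (SD, n = 3 each), and these 2 had drawn attention to the family. AT5G48900 fell from 1419 ± 78.9 to 836 ± 60.7 and AT5G63180 from 1329 ± 52.4 to 875 ± 82.9. The hypothesis that the fall extends beyond the members first seen was tested on the other 12. Their median was -0.306 ± 0.11 (SE), 6 of them fell and 0 rose (camera p = 9.85e-06; adjusted p = 0.0384 with an estimated correlation), in line with a fall of the wider family.

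Glutaredoxins of the plant-specific CC type, small redox proteins, moved in both directions: 6 of 13 measured members rose, 1 fell and 6 did not pass, and 3 of the 6 that rose had drawn attention to the family (camera adjusted p = 0.000369; adjusted p = 0.0334 with an estimated correlation). AT2G47880 rose most. AT1G06830 rose from 462 ± 74.95 to 936 ± 18.1 and AT4G15700 from 36.4 ± 3.97 to 89.3 ± 5.57, while AT5G11930 fell from 161 ± 19.9 to 96.6 ± 13.2, a call lost without auxin 2 (adjusted p = 0.0731), with no filter (0.0517) and without auxin 1 and brassinazole 3 together (0.0952). Among the 10 members not seen before, 3 rose and 1 fell, with a median of 0.274 ± 0.17 (SE) and a camera p of 0.161 (adjusted p = 0.497 with an estimated correlation), so whether the family as a whole is higher stays open.

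Class III peroxidases, secreted enzymes that act on the cell wall, split in direction: 7 of 43 measured members rose and 7 fell. AT3G01190 rose from 304 ± 55.0 to 722 ± 28.8 and AT4G11290 by a log2 change of 1.05 ± 0.0936 (SE), whereas AT4G26010 fell from 880 ± 39.9 to 570 ± 33.97. Over the 39 members not seen before, the median was 0.0917 ± 0.072 (SE; camera adjusted p = 0.793), which decides neither for nor against a shift of the family. Of 39 families of genes that share a symbol stem, also chosen after the data were seen, 1 passed with camera, the EXPA expansins (adjusted p = 0.000219; adjusted p = 0.363 with an estimated correlation).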
